A study of Mus musculus with 3 samples.

How the data were processed

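Total RNA, isolated with TRIzol and a column and labelled by amplification per the labels, from Cyp27b1-knockout mpkDCT cells carried Cy3 and was hybridised to 1-colour Agilent mouse arrays, with 1 array each for vehicle, calcitriol and calcidiol. Per the labels, cells were moved to phenol red-free medium with 2% charcoal-stripped serum 24 h before treatment and stayed in that medium through the 24 h of treatment. Sample titles carry a tag, siCT, that the sources used here do not explain. The label text names the third compound once with an additional hydroxyl group, and its treatment tag, used here, names calcidiol. Per the file headers, all 3 arrays lay on 1 slide and were read in 1 scan, so slide and scan do not separate the groups. Each array had its own position on the slide, so position is confounded with group, and spots near the array edge differed between arrays.

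The deposited scanner files hold the spot intensity on a linear scale. Per the file headers, Agilent Feature Extraction 10.7.1.1 subtracted background, detrended each array and placed probes on the mm9 build, whereas the submitters' processing notes name version 9.5.1.1. No scaling between arrays is recorded in those headers. The deposited value table holds 1 intensity per probe, and its 3 columns each have a log2 median of 3.71 and nearly equal sorted values (98.12% and 97.64% of the calcitriol and calcidiol values equal those of vehicle within a relative 1e-06). Its log2 values correlate across probes with the scanner signals at 0.99992 or more, so its scale is linear. The tool that normalised it is not given in the sources used here. All columns of that table were used, only as an alternative.

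Each array held 62976 spots, of which 59305 were not controls, for 56605 probes. Control spots and spots with an outlier flag were left out, which removed 1489 probes, and no spot was saturated. Signals were log2-transformed and each array's 75th percentile (371.1, 379.8 and 400.8 for vehicle, calcitriol and calcidiol) was subtracted. Of the 56605 probes, 58.29% were named through their accession in a RefSeq gene table of assembly GRCm38.p6, used for names only, and the others (23611) kept the name of the array design, updated where it was a synonym of 1 current gene. A gene was read from its brightest probe. A difference was computed where the probe was well above background on both arrays. A gene with no probe well above background on an array was given a bound instead, the bright array's level over the higher of the lowest signal well above background and the dim probe's own value. Coordinates are those of the probe. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 were used, with statsmodels 0.14.6 for lowess and matplotlib 3.10.9 for figures.

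Precision is limited by the number of arrays. Of 300 probes printed 10 times, 285, 287 and 285 were well above background at every spot on the vehicle, calcitriol and calcidiol arrays. Over these the median coefficient of variation between spots was 7.37% for vehicle, 9.76% for calcitriol and 3.76% for calcidiol. Per the file headers, this measure was out of range on the calcitriol array, and that of the spike-in controls was out of range on the vehicle and calcitriol arrays. Technical errors were taken from the deposited error of the processed signal. The counting step was tested on simulated data for calcitriol against vehicle, with 16378 genes of which 200 were changed: 100% of the 4-fold changes and 52.0% of the changes of exactly 2-fold passed the 2-fold threshold, as did 4 unchanged genes. The simulated noise was the scanner's error only, without variation between cultures or edge effects. It checks the counting and does not give the share of false genes in the real counts.

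No test was run, since each group had 1 array. Genes were described by a 2-fold size threshold. Gene lists, the alternatives, and the rule for naming genes were fixed before the data were examined. Among genes with a symbol, the rule took the 10 highest and 10 lowest differences and the 3 largest bounds in each direction for each hormone against vehicle, 5 and 1 for the direct comparison, list members at least 2-fold apart, the highest and lowest members of each of the 26 lists, and a fixed set of vitamin D, calcium transport and sterol genes. Some genes that the rule takes are not reported here. Random lists were matched on expression in 10 bins, and lists of fewer than 3 measured genes would have been left out. Shared-vehicle values come from 100 simulations. Alternatives were median centring, quantile and cyclic loess normalisation, normexp with an offset of 50 on the raw spot signals followed by quantile normalisation, an offset of 32, other filters on dim probes, keeping outlier spots, the mean over probes, the value table, thresholds of 1.5-fold and 3-fold, and 20 bins. Leaving out the outermost 6 rows and columns was added after the data were seen.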

Results

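Messenger RNA was measured in mpkDCT cells, a mouse cell line derived from the distal convoluted tubule of the kidney, in which Cyp27b1 had been knocked out with CRISPR-Cas9. Cyp27b1 encodes the 1α-hydroxylase that converts 25-hydroxyvitamin D3 (calcidiol) into 1,25-dihydroxyvitamin D3 (calcitriol), the high-affinity ligand of the vitamin D receptor. Cells received vehicle, calcitriol or calcidiol for 24 h, each hormone at 1e-07 M, and each group was measured on 1 array. The comparisons ask which genes differed with each compound in cells whose gene for the converting enzyme had been targeted. The share of spots well above background was 50.98% on the vehicle array, 49.92% on the calcitriol array and 49.7% on the calcidiol array. With 1 array per group no difference has a replicate check and no p-value is given. Values written with ± carry the technical error that the scanner software assigns to the spots, which leaves out variation between cultures. The median of this error was 0.2 on the log2 scale in all 3 comparisons, although replicate spots varied unequally between arrays. It is therefore not a spread measured here.

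The targeted gene was examined first. The Cyp27b1 probe (chromosome 10, 126489922 to 126489981 on mm9) was not well above background on any of the 3 arrays, with processed signals of 2.91 for vehicle, 7.05 for calcitriol and 3.82 for calcidiol, so no fold is given. Where this probe lies relative to the edited part of the gene is not given in the sources used here, so it does not check the knockout. Vdr, the vitamin D receptor, was detected on all 3 arrays and differed from vehicle by -0.20 ± 0.20 on the log2 scale with calcitriol and by -0.29 ± 0.20 with calcidiol. Rxra, its heterodimer partner, differed by -0.11 and -0.40 by its brightest probe and by 0.11 and 0.18 by its other probes. Cyp2r1, a 25-hydroxylase, was 1.05 higher on the log2 scale with calcidiol and 0.40 higher with calcitriol, and Gc, the vitamin D binding protein, was at -2.14 with calcitriol and -0.79 with calcidiol. Lrp2, the endocytic receptor megalin, was 1.37 higher with calcitriol and 0.88 higher with calcidiol by its brightest probe, and 0.86 and 0.07 higher by its other probes.

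Calcitriol was first set against vehicle. Cyp24a1, the 24-hydroxylase that inactivates vitamin D metabolites (probe on chromosome 2, 170308865 to 170308924, mm9), was not well above background with vehicle and was at least 398-fold higher with calcitriol, where its processed signal was 5440. S100g, the calcium-binding protein calbindin-D9k (chromosome X, 159400032 to 159400091), was at least 14.7-fold higher. Krt17, a type I keratin (chromosome 11, 100117584 to 100117643), was 126-fold higher, a log2 difference of 6.98 ± 0.30, and Srcin1, an inhibitor of SRC kinase signalling (chromosome 11, 97370654 to 97370713), was 39.4-fold higher. Cldn2, a tight-junction protein that forms paracellular cation channels (chromosome X, 136345244 to 136345303), was 17.4-fold higher, at 4.12 ± 0.26, and Spp1, which encodes osteopontin (chromosome 5, 104869788 to 104869847), was 14.5-fold higher, at 3.86 ± 0.20. The vehicle signals of Krt17 (18.4), Srcin1 (15.4) and Cldn2 (26.0) were near the lowest well above background on that array (13.36). The sizes of these 3 differences are therefore uncertain.

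Among the other genes with the highest differences, Slco1a6, an organic anion transporter, was 14.7-fold higher, the cytochrome P450 gene Cyp1b1 12.3-fold, the adhesion molecule gene Alcam 10.3-fold, Npr3, the natriuretic peptide clearance receptor, 10.1-fold, Dcdc2a 9.82-fold and Stac 9.70-fold. Another Npr3 probe gave a log2 difference of 0.86 against 3.34 for the brightest one, whereas another Dcdc2a probe gave 3.45 against 3.30. Vehicle signals of Slco1a6 (24.7), Dcdc2a (22.9) and Stac (26.6) were also near the lowest well above background (13.36). Mep1a, the metalloprotease meprin alpha, was at least 20.9-fold higher and the defensin gene Defb29 at least 20.4-fold higher, the latter from a spot in the row or column numbered 2 from the array edge. The lowest differences included the extracellular matrix genes Postn (periostin), 6.19-fold lower, and Dcn (decorin), 5.16-fold lower, together with the growth factor gene Fgf1, 6.67-fold lower, Sema3d, a semaphorin, 5.77-fold lower, and the neurotensin receptor gene Ntsr1, 4.48-fold lower. Other probes of Postn gave -2.55 beside -2.63 for the brightest. Acsl3, Masp1, Rad21, Ufc1 and Atp1b2 complete the 10 lowest, at log2 differences of -3.41, -2.97, -2.75, -2.29 and -2.18. All of these last 5 genes are read from spots within 5 rows or columns of the array edge, and another Acsl3 probe differed by only -0.09. Nfatc2, Jakmip3 and Serpina3h were not well above background with calcitriol and were at least 10.1-fold, 5.32-fold and 4.13-fold lower, the last from a spot in the outermost row or column.

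Of 16653 genes measured on both arrays, 160 were at least 2-fold higher and 271 at least 2-fold lower with calcitriol. A further 78 and 102 genes, detected on only 1 of the 2 arrays, were at least 2-fold higher and lower by their bound. The counts of higher and lower genes were 93 and 104 with normexp background correction and quantile normalisation, 93 and 147 without genes below the 25th percentile of signal, and 345 and 627 with detection on at least 1 array, and an offset of 32 gave 138 lower genes. Of 47 higher genes with another detected probe, 45 had that probe in the same direction, 38 of them by at least 0.5 on the log2 scale, as did 58 of 63 lower genes, 39 of them by at least 0.5. Centring on the array median moved the median of all genes by 0.12 on the log2 scale and the share of higher genes among those 2-fold apart from 37.12% to 54.81%, quantile normalisation moved that share to 43.52%, and normexp background correction together with quantile normalisation moved it to 47.21%.

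**Figure D1:**
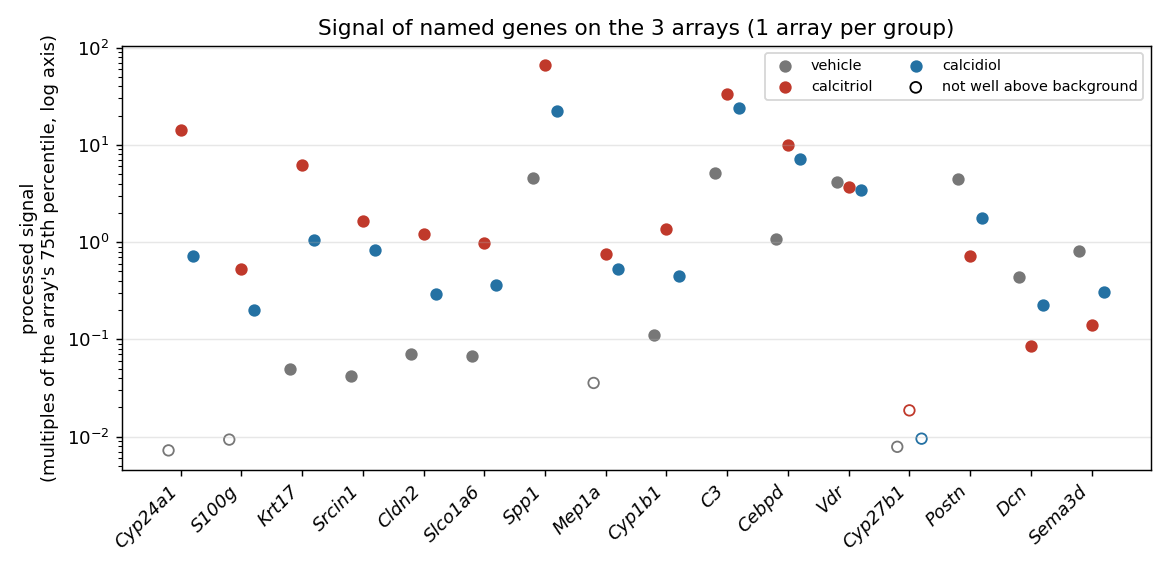
Processed signal of 16 named genes as multiples of each array's 75th percentile on a log axis; each point is 1 array and open points were not well above background. Cyp24a1 and S100g are open with vehicle and filled with both hormones, and Cyp27b1 is open on all 3 arrays.

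Calcidiol was next set against vehicle. Cyp24a1 was higher by at least 4.32 on the log2 scale and S100g at least 5.62-fold higher. Krt17 was 21.4-fold higher (log2 4.42 ± 0.30), Srcin1 19.9-fold, Slco1a6 5.48-fold and Spp1 4.91-fold, all of them also among the 10 highest with calcitriol, and Cldn2 was 2.07 ± 0.26 higher on the log2 scale. The same near-background vehicle signals of Krt17, Srcin1, Slco1a6 and Cldn2 leave the sizes of these differences uncertain. Mep1a was at least 14.6-fold higher. Cebpd, a C/EBP transcription factor, was 6.64-fold higher, C3, a complement component, 4.67-fold, Mgll, which encodes monoacylglycerol lipase, 4.34-fold, and Samd11 4.30-fold, at 2.10 ± 0.20. The Samd11 difference of calcitriol from vehicle, 1.33, became -0.20 with the mean over its probes. Stra6, a receptor for retinol binding protein, was 4.16-fold higher with calcidiol and 1.92-fold with calcitriol. Pum2 and Bcl7a also ranked among the 10 highest, at 3.53 and 2.15, but both lie within 2 rows or columns of the array edge and their other probes gave 0.04 and -0.17.

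The genes lowest with calcidiol were Tubgcp5, 5.10-fold lower, and Sult1d1, a sulfotransferase, 3.29-fold lower, followed by Nfatc2 (3.15-fold), Igfbp4 (2.71-fold), Sema3d (2.66-fold), Afm (2.60-fold), Masp1 (2.52-fold), Postn (2.51-fold), Fam89a (2.40-fold) and Gucy1a2 (2.37-fold). Other Tubgcp5 probes gave -0.04, and other Sult1d1 probes gave -0.91. The calcidiol signals of Igfbp4 (21.8), Afm (24.6) and Gucy1a2 (26.2) were near the lowest well above background on that array (17.85). Masp1 was read from a spot in the row or column numbered 5 from the array edge. Jakmip3 and Sec31b were at least 4.34-fold and 2.90-fold lower. Of 16646 genes measured on both arrays, 142 were at least 2-fold higher and 24 at least 2-fold lower, with 129 and 27 more by their bound. These counts depend on the treatment of dim signals: they were 76 and 4 with normexp background correction and quantile normalisation, 77 and 7 with an offset of 32, 70 and 7 without genes below the 25th percentile of signal, and 447 and 228 with detection on at least 1 array. In 14 of 21 higher genes with another detected probe that probe was in the same direction, in 10 of them by at least 0.5 on the log2 scale, and in 4 of 4 lower genes, in 2 of them by at least 0.5.

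The compounds, which differ by the 1α-hydroxyl group that calcitriol carries, were compared directly at the same dose and time. Cyp24a1 was 19.9-fold higher with calcitriol than with calcidiol, a log2 difference of 4.32 ± 0.20. Stac was 6.59-fold higher, Rapsn 5.94-fold, Krt17 5.90-fold and Defb29 5.62-fold, and Bhmt was at least 6.84-fold higher. The calcidiol signal of Rapsn (21.6) was near the lowest well above background on that array (17.85). Cldn2 was 4.14-fold higher, Spp1 2.96-fold and S100g 2.61-fold, at 1.38 ± 0.22. For C3, at 0.46 ± 0.20, Cebpd, at 0.47 ± 0.20, and Mep1a, at 0.52 ± 0.21, the compounds were less than 2-fold apart. In the other direction Stra6 was at -1.12 ± 0.21, Cxcl1, a neutrophil chemokine, at -1.20 ± 0.20, and Il22ra1 was at least 6.12-fold lower with calcitriol. The 5 lowest genes, Acsl3, Mfsd2b, Pum2, Ufc1 and Rad21, were between 18.0-fold and 6.42-fold lower, and all lie within 5 rows or columns of the array edge. Of 16499 genes, 77 were at least 2-fold higher and 232 at least 2-fold lower with calcitriol. Of those with another detected probe, that probe was in the same direction for 17 of 20 higher and 29 of 44 lower genes, and by at least 0.5 on the log2 scale for only 13 and 11 of them. Centring on the median moved the median of all genes by 0.19 and gave 133 higher and 133 lower genes, and normexp background correction together with quantile normalisation gave 34 and 126. An offset of 32 gave 48 and 113, leaving out genes below the 25th percentile of signal 43 and 128, and detection on at least 1 array 223 and 628.

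Across 16378 genes measured on all 3 arrays, the differences of calcitriol and calcidiol from the shared vehicle array correlated at Pearson r = 0.525, across genes that are not independent replicates. Simulated arrays with no effect and the scanner's error gave a mean r of 0.491 from the shared vehicle alone. That error was near equal on the 3 arrays and leaves out variation between cultures. Replicate spots varied unequally between arrays, so 0.491 is not a full baseline and r is not read as an excess. The covariance was 0.0582, against 0.0239 in the simulations, a difference of 0.0343. Of these genes, 156 were at least 2-fold higher with calcitriol, 131 with calcidiol and 60 with both, where independent lists would share 1.25 and the simulations 0.14. Of the lower genes, 270 with calcitriol and 20 with calcidiol, 16 were shared, against 0.33 for independent lists and 0.17 in the simulations. The simulations passed a mean of only 2.12 higher and 2.07 lower genes with calcitriol, so their overlap was small by construction. Independent lists ignore the shared vehicle array, so neither value measures a shared response. The overlaps of higher and lower genes were 30 and 2 with normexp background correction and quantile normalisation, 39 and 5 with an offset of 32, 41 and 3 without genes below the 25th percentile of signal, and 170 and 147 with detection on at least 1 array. The size of the lower overlap thus depends on the treatment of dim signals. Part or all of the excess over these values may come from the single vehicle culture and its array, which both differences share and which cannot be split. Among the 156 genes chosen on calcitriol, 146 had the larger difference with calcitriol and the median ratio of calcidiol to calcitriol log2 differences was 0.524. Among the 131 genes chosen on calcidiol, 50 had the larger difference with calcitriol.

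**Figure D2:**
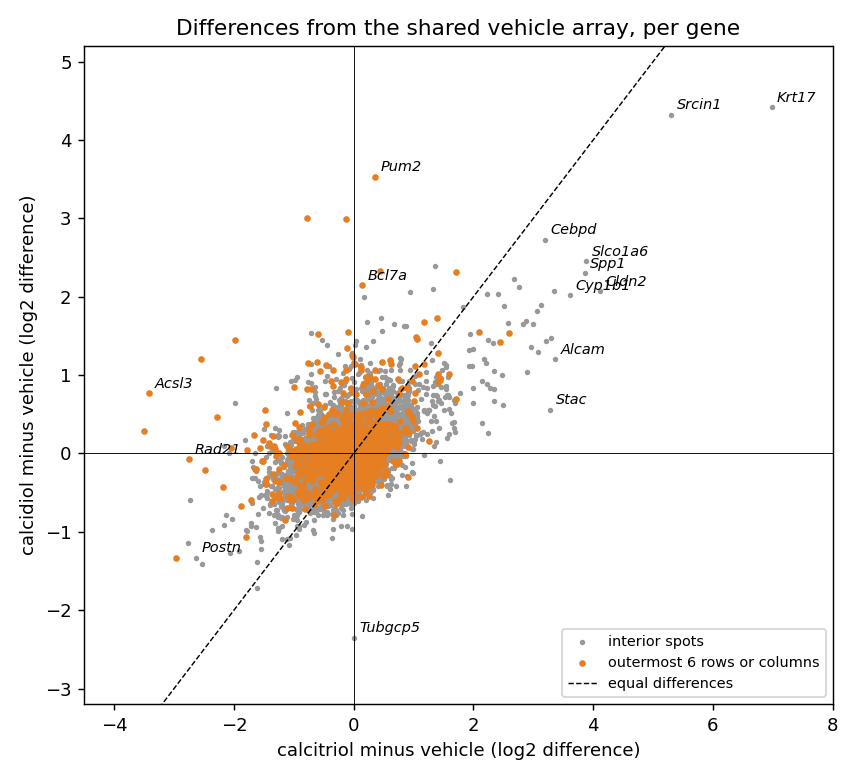
Log2 difference of calcidiol from vehicle against that of calcitriol from the same vehicle array, 1 point per gene, with genes read from the outermost 6 rows or columns in orange and equal differences on the dashed line. Krt17 lies at 6.98 and 4.42, below the dashed line, while Pum2 and Acsl3 are edge spots far from it.

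Gene groups were described by the median log2 difference of lists fixed before the data were examined and by its percentile among 10000 random lists matched on expression. Of 78 pairs of list and comparison, 19 lay outside the central 95% of random lists, where random draws of unrelated genes give 0.65 of 26 lists in each tail of a comparison. Genes of a list can move together between any pair of cultures, lists share genes, and the comparisons share arrays. The 19 is therefore a description and not a test against chance. Centring on the array median instead of the 75th percentile adds 1 value to every gene of a comparison, so it moves medians and leaves percentiles as they were. Of 17 measured vitamin D receptor target genes, 2 were at least 2-fold higher with calcitriol, Spp1 and Cldn2, and 2 lower, the cell-cycle inhibitor gene Cdkn1a at -1.46 and the phosphatase gene Dusp10 at -1.09. The list median was -0.05 with calcitriol, at the 30.61 percentile, 0.03 with the bounded genes Cyp24a1 and S100g included, and 0.07 after centring on the median. With calcidiol it was -0.09, at the 9.15 percentile, -0.03 with bounded genes included and -0.15 after centring. In the list of calcium and magnesium transport genes, Trpv5, Trpv6, Calb1, Slc8a1, Kl and Trpm6 were not well above background on any array. Atp2b1, the plasma membrane calcium pump, differed by 0.25 with calcitriol and 0.03 with calcidiol by its brightest probe, and by -0.28 and -0.02 by its other probes. The median of that list was 0.22 higher with calcitriol than with calcidiol, at the 98.55 percentile over 9 genes, and 0.15 higher, at the 92.88 percentile, over 8 genes without the array edge. After centring it was 0.40. Among distal tubule and sodium handling genes the thiazide-sensitive cotransporter gene Slc12a3 was not well above background on any array, and Sgk1, a kinase that regulates sodium transport, was 1.39 higher with calcitriol and 1.73 higher with calcidiol on the log2 scale, from a spot in the outermost row or column.

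Of 25 measured sterol synthesis genes 24 were below 0 with calcitriol, none by 2-fold, and the median of -0.32 lay below all 10000 random lists. Fdft1 (squalene synthase) was at -0.74, from a spot in the row or column numbered 2 from the edge, and at -0.16 by its other probes. Insig1, a regulator of the pathway, was at -0.49. With calcidiol the median was -0.11, at the 0.37 percentile, and 21 of 25 genes were below 0. Centred on the array median the sterol list was at -0.19 with calcitriol and -0.17 with calcidiol, while the median of all genes moved to 0.12 and -0.07. Fatty acid synthesis genes had medians of -0.20 with calcitriol, at the 0.23 percentile, and -0.15 with calcidiol, at the 0.48 percentile. After centring they were -0.08 and -0.21, but relative to all genes the order of the compounds did not turn. In the direct comparison the fatty acid median was -0.04, at the 15.32 percentile. Hypoxia and glycolysis genes had a median of -0.32 with calcitriol, below all random lists, with 17 of 19 below 0. In that list the hexokinase gene Hk2 was at -1.21 and the phosphofructokinase gene Pfkp at -1.04. With calcidiol the median was -0.07, at the 4.61 percentile, and centring gave -0.19 with calcitriol and -0.13 with calcidiol. Immediate early and growth factor response genes had a median of -0.46 with calcitriol, below all random lists, with Egr2 at -1.29 and Egr1 at -1.12. With calcidiol it was -0.16, at the 0.60 percentile. Without a filter on dim probes the calcidiol median was 0.01, while that of all genes was 0.13. Centring gave -0.34 with calcitriol and -0.22 with calcidiol. In the direct comparison the sterol and glycolysis lists again lay below all random lists, at -0.24 and -0.25, and the immediate early list was at -0.27, at the 0.10 percentile. After centring these 3 direct medians were -0.05, -0.06 and -0.08, while the median of all genes moved to 0.19.

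Markers of fibroblast, endothelial, podocyte and macrophage cells, listed as other cell types a kidney sample could hold, had medians of -0.28 with calcitriol, at the 1.05 percentile, and -0.22 with calcidiol, at the 0.16 percentile. Without a filter on dim probes these medians were 0.01 and 0.16, where those of all genes were 0.03 and 0.13, and after centring -0.16 and -0.29. Without the array edge they were -0.58, at the 0.02 percentile, and -0.18, at the 1.80 percentile. Within that list Postn, Dcn and Col1a1 were at -2.63, -2.37 and -1.28 with calcitriol, and Ptprc was at 0.04. Acta2 was at 0.08 by its brightest probe, in the row or column numbered 2 from the edge, and at -1.09 by its other probes. Extracellular matrix and TGF-β response genes, which share Col1a1 with it, had medians of -0.10 with calcitriol, at the 2.77 percentile (0.03 after centring on the median, and -0.16 at the 0.29 percentile without the array edge), and -0.21 with calcidiol, below all random lists. In this list Snai1, a transcription factor, was at -1.20 with calcitriol and Spp1 was higher. Inflammatory NF-κB target genes had medians of 0.17 with calcitriol, at the 99.34 percentile, and 0.10 with calcidiol, at the 98.20 percentile, or 0.29 and 0.04 after centring. The chemokine genes Ccl20 (2.90-fold and 2.15-fold) and Cxcl5 (2.44-fold and 2.66-fold) were higher with both compounds, Ccl5 was at -1.32 on the log2 scale with calcitriol, and Cxcl1 was at -0.18 with calcitriol and 1.03 with calcidiol. Circadian clock genes had medians of -0.15 with calcitriol, at the 6.80 percentile, and -0.23 with calcidiol, at the 0.02 percentile, or -0.03 and -0.29 after centring. The 30 cell proliferation genes, none of them 2-fold apart, had medians of 0.04 and -0.06, inside the random range, or 0.17 and -0.12 after centring.

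**Figure D3:**
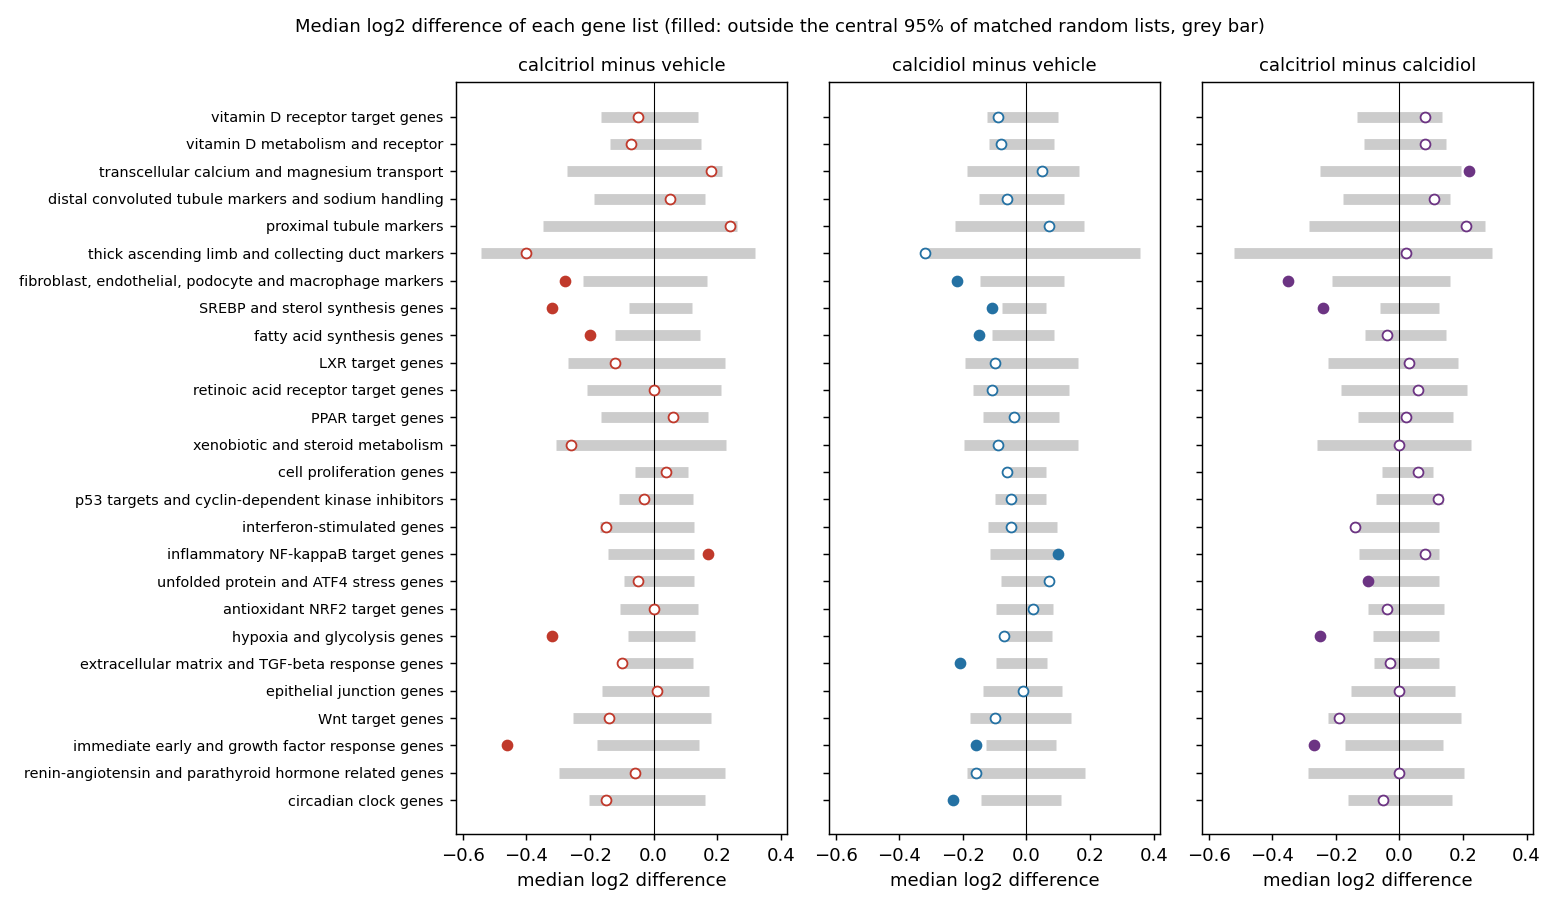
Median log2 difference of each of the 26 gene lists in the 3 comparisons; grey bars span the central 95% of random lists matched on expression and filled points lie outside. Sterol synthesis genes lie at -0.32 with calcitriol and -0.11 with calcidiol, which centring on the array median moves to -0.19 and -0.17. The same centring moves the median of all genes to 0.12 and -0.07.

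Spots at least 2-fold apart were more frequent near the edge of the array, mainly in 1 direction of each comparison. In the outermost 6 rows or columns 4.17% of measured spots were at least 2-fold lower with calcitriol than with vehicle, against 1.22% in the interior. For calcidiol above vehicle the shares were 2.85% and 0.558%, and for calcitriol below calcidiol 5.49% and 0.869%. In the opposite directions they were 1.45% and 0.862% for calcitriol above vehicle, 0.156% and 0.127% for calcidiol below vehicle, and 0.403% and 0.393% for calcitriol above calcidiol. Without these rows and columns, a filter chosen after seeing the data, 144 genes were higher and 222 lower with calcitriol, 103 higher and 21 lower with calcidiol, and 73 higher and 162 lower in the direct comparison.

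**Figure D4:**
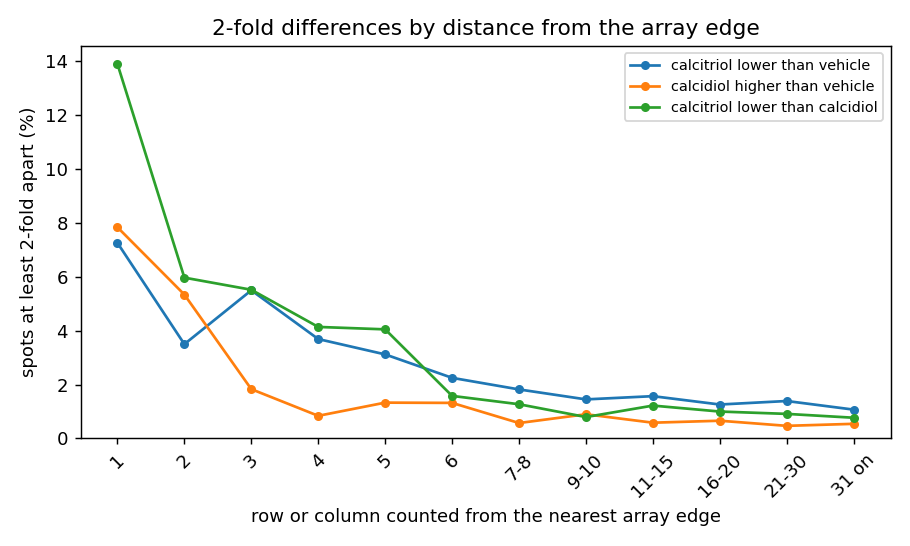
Percent of measured spots at least 2-fold apart against the row or column counted from the nearest array edge, for the directions most affected. In the outermost row or column 13.9% of spots were lower with calcitriol than calcidiol, against 0.769% from row or column 31 inward.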

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

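The spike-in control spots, which enter no comparison, were brighter on the calcitriol array than on the vehicle array. After scaling to the 75th percentile, the 7 spike-ins with signals above 20 on every array had a median log2 difference of 0.15, from 0.11 to 0.21. On the calcidiol array the median difference from vehicle was -0.07.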

How the results depend on the processing

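No paired analysis was possible because each group had 1 array and no test was run. For the counts, the shared response and the number of lists outside the random range, 91 recomputed values stayed within the tolerance (1.5 times for counts, 10% for the correlation and slope) and 54 did not, and the cause was not tested beyond what each alternative's construction shows. Quantile and cyclic loess normalisation, the value table, outlier spots kept, the mean over probes and, added after the data were seen, leaving out the array edge kept all of these values within it. The number of list and comparison pairs outside the random range, 19, lay between 18 and 27. Counts below are higher and lower for calcitriol against vehicle, then calcidiol against vehicle, then calcitriol against calcidiol. Median centring gave 133 and 133 in the direct comparison. Normexp with quantile normalisation gave 93 and 104, 76 and 4, and 34 and 126, with 30 and 2 shared genes and a slope of 0.353 (0.416 in the main setting). An offset of 32 gave 138 lower, 77 and 7, and 48 and 113, with 39 and 5 shared. Detection on at least one array gave 345 and 627, 447 and 228, and 223 and 628, with 170 and 147 shared. No filter gave 1400 and 1662, 1704 and 910, and 915 and 1944, with 391 and 534 shared and a slope of 0.463. Leaving out genes below the 25th percentile of signal gave 93 and 147, 70 and 7, and 43 and 128, with 3 shared lower genes. By construction a 1.5-fold threshold gave more genes, 563 and 1041, 472 and 221, and 357 and 916, and a 3-fold threshold fewer, 66 and 47, 40 and 3, and 23 and 53. Of the recomputed list medians 855 stayed within 1 SD of random lists, 152 moved further, some of them across 0, and 4 that lay outside the random range changed sign: unfolded protein and ATF4 stress genes in the direct comparison became 0.08 with median centring, and without a filter fibroblast, endothelial, podocyte and macrophage markers became 0.01 with calcitriol and 0.16 with calcidiol, and immediate early genes 0.01 with calcidiol. The median of all genes moved in these settings too. It was 0.19 in the direct comparison with median centring, and 0.03 with calcitriol and 0.13 with calcidiol without a filter. These 4 sign changes are therefore not read as a change of direction relative to other genes. Of the values of named genes 3145 stayed within their technical error, 318 moved further and 3 of those 2-fold apart changed sign. Of the 52, 34 and 36 named genes 2-fold apart in the 3 comparisons, 35, 21 and 24 stayed so with normexp, 45, 26 and 26 with the offset, and 47, 32 and 30 with median centring. The 3 sign changes were these: Samd11 became -0.20 for calcitriol with the mean over probes, and without the array edge Bcl7a became -0.17 for calcidiol and 0.24 in the direct comparison. Cyp27b1 was not well above background on any array, so no fold is given for it. Signal over background limits what can be said of dim genes. That every count was higher without a filter than with it does not measure this limit, since the filter only removes genes.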

Other observations

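Several gene groups not described above held single genes at least 2-fold apart. Among thick ascending limb and collecting duct markers, of which 4 were measured, the keratin gene Krt7 was 1.99 higher on the log2 scale with calcitriol and 0.83 higher with calcidiol. Among renin-angiotensin and parathyroid hormone related genes, Edn1 (endothelin-1) was 1.39 higher and Agt (angiotensinogen) was at -1.58 with calcitriol, against 0.73 and -0.56 with calcidiol. Gclc, a subunit of the enzyme that starts glutathione synthesis, was at -1.05 with calcitriol, the Wnt target gene Lef1 at -1.33, Ppara at -1.02 (-0.46 by its other probes), and Tgm2, a retinoic acid target gene, at 1.02. Fabp4 was 1.20 higher with calcidiol. Hsp90b1 was at -1.56 with calcitriol and 0.07 with calcidiol, from a spot in the row or column numbered 4 from the array edge.

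List medians inside the central 95% of random lists for both hormones are given for calcitriol and then calcidiol, followed by both values after centring on the array median. They were 0.24 and 0.07 for proximal tubule markers (0.37 and 0.01), 0.05 and -0.06 for distal tubule and sodium handling genes (0.17 and -0.12), -0.07 and -0.08 for vitamin D metabolism and receptor genes (0.05 and -0.14), and -0.40 and -0.32 for thick ascending limb and collecting duct markers (-0.28 and -0.38). They were -0.12 and -0.10 for LXR targets (0.00 and -0.16), 0.06 and -0.04 for PPAR targets (0.18 and -0.10), -0.26 and -0.09 for xenobiotic metabolism (-0.14 and -0.15), and -0.03 and -0.05 for p53 targets (0.10 and -0.12). Retinoic acid receptor targets had 0.00 and -0.11 (0.12 and -0.17), antioxidant NRF2 targets 0.00 and 0.02 (0.13 and -0.04), and renin-angiotensin and parathyroid hormone related genes -0.06 and -0.16 (0.06 and -0.23). Interferon-stimulated genes had -0.15 and -0.05 (-0.03 and -0.11), unfolded protein and ATF4 stress genes -0.05 and 0.07 (0.07 and 0.00), epithelial junction genes 0.01 and -0.01 (0.13 and -0.07), and Wnt targets -0.14 and -0.10 (-0.02 and -0.16). In the direct comparison the unfolded protein list was at -0.10, at the 1.1 percentile, and at 0.08 after centring on the median. Without the array edge the thick ascending limb list with calcidiol lay at the 2.26 percentile, against 3.02 with it, and antioxidant NRF2 targets in the direct comparison at the 1.13 percentile, against 14.22.

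The tests of the array edge, of the spike-in slope, of selection in its present form and of other probes as divided between lists, and the setting that leaves out the edge, were chosen only after the results they bear on had been seen at least in part. The excess of 2-fold differences near the array edge was set against a second probe of the same gene lying in the interior. That probe gave a difference of at least 0.5 on the log2 scale in the same direction for 33.3% of edge genes (17 of 51) and for 66.2% of interior genes (86 of 130), counts pooled over the 3 comparisons, in which a gene can appear more than once. This is consistent with spot defects at the edge as a source of part of the edge genes' differences. No biological explanation was tested for this pattern.

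For the smaller response to calcidiol at genes chosen on calcitriol, the slope of log2 spike-in signals on the calcidiol array against the vehicle array was 1.01, which argues against a compressed signal scale. With genes chosen on calcidiol instead and the array edge left out, 46.2% (42 of 91) had the larger difference with calcitriol, against 131 of 135 genes chosen on calcitriol. The rule set beforehand for selection, at most 1 gene in 2, was met, but it was replaced after the result was seen: selection alone on arrays of like noise would mirror the 131 of 135, and replicate spots varied by 9.76% with calcitriol and 3.76% with calcidiol, so how far selection contributes stays open. Cyp24a1 and S100g were named before the data were examined, so selection does not apply to their direct differences of 4.32 and 1.38. A difference in potency between the compounds stays open and untested, as do a difference between single cultures and the label text that names the third compound in another way.

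The lower medians of sterol, glycolysis and immediate early genes with calcitriol were below all random lists after correction for trends in signal level and probe GC content (highest percentile 0.0) and without the array edge (0.0), which argues against these as the whole cause. Members with another probe had medians of -0.24 for sterol genes (16 of 25) and -0.30 for glycolysis genes (9 of 19), against the choice of probe there, while the -0.65 of immediate early genes rests on 3 of 17 and leaves it open. The size depends on the scaling: centring on the array median gave -0.19, -0.19 and -0.34 against vehicle and -0.05, -0.06 and -0.08 against calcidiol. Centring also moved the median of all genes to 0.12 and 0.19, so the distance to other genes was unchanged. Array medians (16.3, 15.3 and 18.4 for vehicle, calcitriol and calcidiol) lay near the lowest signals well above background (13.36, 13.82 and 17.85). Scaling to the spike-ins, 0.15 higher with calcitriol than vehicle, would lower the medians against vehicle and was not run. A response to calcitriol is 1 hypothesis, and a difference between single cultures may equally be the source, since each group was measured on 1 array.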
